A study of Mus musculus with 2 samples.

How the data were processed

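The study measured gene expression in single live CD4+ T cells, sorted by flow cytometry from small intestinal lamina propria of naive C57BL6/J mice and of mice at day 30 after infection with Heligmosomoides polygyrus. Cells of several mice were pooled for each condition and processed with the 10x Genomics 5' GEX V2 kit, with about 10000 cells captured per pool per the labels. The deposited values were UMI counts per gene and barcode, in a filtered matrix made by the authors with Cell Ranger 5.0.1 on GRCm38, per the submitters' processing notes. The gene annotation was not given in the sources used here. The counts were whole numbers, with 58830114 UMIs in 15282 barcodes of the naive and 50838972 UMIs in 11234 barcodes of the infected library. Of 53465 gene identifiers, 53360 were found in GENCODE M21, which gave positions and overlapping exons.

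A cell passed with at least 500 genes, at least 1000 UMIs and less than 10% mitochondrial UMIs, which left 12448 naive and 8322 infected cells and 56784640 and 48641273 UMIs. Scrublet, as in scanpy 1.11.5, was run per library at an expected rate of 0.08. It called 1 naive and 0 infected doublets, 0.00481% of cells and under the 0.5% set as a sign of failure, so every passing cell was kept. Counts were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes were chosen with Th2, HIF pathway, HIF target, T cell receptor, immunoglobulin, ribosomal, mitochondrial, sex-linked and handling genes left out. Then 30 principal components, 15 neighbours, a shared neighbour graph and Leiden clustering at resolution 1.0 gave 19 clusters of both libraries together. No correction between libraries was made, since library and group are the same. A cluster was named for a T cell type when at least 3 of its markers were 2-fold above the other cells and were read in at least 5% of its cells. It stayed unnamed when its median UMI count in either library was below 1/3 of that of all passing cells of the library, or when at least 3 pancreatic genes were among its 10 leading genes. These naming thresholds and the pancreatic list were set after the data were seen. The gene lists, markers, filters and other settings, and the naming rule for genes, were chosen before the data were examined, and 336 of their 342 genes were in the files.

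The classes were Th2-like (clusters 1, 6 and 13), central-like (0 and 11), Treg-like (4, 8 and 14), Th1-like (5), Tfh-like (9), innate-like (3), interferon-stimulated (16) and cycling (17). Clusters 2 and 10 had fewer than 3 markers, clusters 7 and 12 had few UMIs, and pancreatic genes led clusters 15 and 18. The innate-like cluster (1299 naive and 67 infected cells) was set aside from the expression comparisons. Interferon-stimulated cells were 1.38% of naive (1.18 to 1.60) and 0.216% of infected cells (0.128 to 0.342). Clusters 7, 10, 12 and 18 were 3.72%, 4.28%, 1.53% and 0.0482% of naive and 7.25%, 2.04%, 4.23% and 0.144% of infected cells.

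UMIs were summed over the cells of a library or class and divided by all gene UMIs. With 1 library per group no variance between animals could be estimated, so no p-value, standard error or count of differing genes was made. Each level has an exact Poisson interval, each ratio an exact interval from the conditional binomial distribution, and each share a Clopper-Pearson interval, all at 95%. A gene with 0 UMIs in a group was compared with 3 UMIs over that group's total. Where 0 cells had a UMI of a gene, the limit given is 3 cells over all cells counted, and it limits cells with a UMI at that depth, not cells that express the gene. The genes named are the HIF pathway genes, genes whose shares of cells were measured (Il4, Il5, Il13, Gata3, Epas1, Hif1a, Foxp3, Tbx21, Ifng, Il17a and Mki67), up to 4 members of each list with the largest ratio in either direction, and the 12 highest and 12 lowest ratios whose interval excludes equal levels, the last among genes with at least 100 UMIs. Other named genes were chosen after their values were seen. List medians used members with at least 20 UMIs and were placed among 10000 random lists drawn from the same 20 expression bins. These percentiles describe the libraries at hand and are no test between groups. For shares of cells with a UMI, each cell was thinned to 2000 UMIs without replacement.

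Marker lists served to look for other cells and gave these summed levels in the naive and infected library. They were 246 and 203 CPM for B cells, 58.0 and 30.0 for plasma cells, 114 and 189 for myeloid cells, 26.3 and 10.5 for epithelium, 72.0 and 41.5 for stroma and endothelium, 0.369 and 1.74 for mast cells and granulocytes, and 0.0389 and 2.77 for erythroid cells. They were 938 and 2409 CPM for innate lymphoid cells, a list that shares Gata3, Il7r and Nmur1 with Th2 cells, 174 and 92.3 for cytotoxic cells, 22.9 and 17.3 for innate-like T cells and 4574 and 4545 for all T cells. The class markers summed to 464 and 2126 CPM for Th2, 85.5 and 41.5 for Th17, 663 and 497 for Th1, 1693 and 893 for Treg, 299 and 124 for Tfh, 3398 and 665 for central-like, 71.3 and 55.8 for cycling and 352 and 282 for interferon-stimulated cells. Epcam made up 22.5 and 6.00 CPM of the epithelial sum and Pecam1 71.5 and 40.9 CPM of the stromal and endothelial sum. Epcam was a leading gene of Treg-like cluster 4, and Pecam1 was read in Th2-like cells too, so both sums are no measure of other cells. The B cell and myeloid sums rested mostly on Ighm (236 and 199 CPM) and Cst3 (105 and 167 CPM), and are no measure of such cells either. A cluster with enough markers of more than 1 class was named for the class with the most markers among its 10 leading genes, and at equal numbers for the class with the larger share of its markers over the threshold. No cluster was named for Th17 cells or for another cell lineage, but clusters 14 and 5, named Treg-like and Th1-like, also had 5 and 3 Th17 markers over the threshold, and the innate-like cluster had 3 markers of cytotoxic cells.

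The steps were tested on simulated data made from these libraries with known shifts. Over 10369 genes of the whole library, 50 genes each with a true log2 ratio of 1, 2, -1 and -2 had medians of 1.01, 2.01, -0.99 and -2.00, and their intervals held the truth in 98%, 96%, 92% and 94% of cases. Over 9538 genes of cells with a UMI of Il4, Il5 or Il13 the medians were 1.00, 1.99, -0.99 and -2.00, with 98%, 92%, 90% and 100%. Unshifted genes were held in 95.3% and 95.0%. The simulated counts followed the Poisson distribution that the intervals assume. This coverage therefore checks the calculation and not the spread between cells or mice. Of 100 simulated lists of 20 genes shifted by 0.5, 100 lay outside the central 95% of the random lists in either comparison, against 6 and 7 of 100 unshifted lists. Clustering gave 100% of 3000 simulated cells of 3 profiles their class. The profiles came from cells picked by marker genes and had no spread within a profile, an easier case than the real cells. Thinning gave shares of 32.3% and 32.9% at depths of 3000 and 8000 UMIs where the truth was 33.0%.

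The alternatives were other scalings (median-of-ratios, CPM without ribosomal, mitochondrial and receptor genes, mean over cells), other filters (5% mitochondrial, 200 genes without a UMI minimum), called doublets kept, every passing cell kept, Leiden resolutions of 0.6 and 1.5, 50 components, Th2 and HIF genes among the variable genes, thinning to 1000 UMIs or none, list members with at least 100 UMIs, list means, Th2-like cells defined by an Il4, Il5 or Il13 UMI, and infected classes weighted by naive class shares. After the data were seen, 5 more were added, namely leaving out the 8% of cells with the highest doublet scores, counting cluster 2 or cluster 15 as Th2-like, leaving out the clusters led by pancreatic genes, and leaving out every unnamed cluster. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Barcodes that failed the filters (2834 naive and 2912 infected) were left out of every comparison. 1 further test of pancreatic transcripts, planned before the results, is not used here.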

Results

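Live CD4+ T cells were purified by flow cytometry from the lamina propria of the small intestine of C57BL6/J mice and profiled by 10x Genomics 5' single-cell gene expression. There were 2 libraries. The naive library held pooled cells of uninfected mice, and the infected library held pooled cells of mice 30 days after infection with Heligmosomoides polygyrus, a nematode that lives in the mouse small intestine. Each group was 1 library (n = 1), so no test between groups was possible and each difference given here has no replicate check. The naive library held 58830114 UMIs in 15282 barcodes and the infected library 50838972 UMIs in 11234 barcodes. Of these, 12448 naive cells (81.5%, 80.8 to 82.1) and 8322 infected cells (74.1%, 73.3 to 74.9) passed the filters. The median passing cell held 4020 UMIs and 1714 genes in the naive library and 5592.5 UMIs and 2224 genes in the infected library, and mitochondrial genes took 1.98% and 1.86% of its UMIs. Ranges in brackets are exact 95% intervals (Clopper-Pearson for shares, Poisson for levels and the conditional binomial for ratios), and they cover counting error only. Levels are CPM, the UMIs of a gene scaled to the same total of gene UMIs in each library or class, and log2 ratios are infected over naive.

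Transcripts of cell types other than T cells were measured as a background. Ighm, the heavy chain gene of B cell receptors, was at 236 CPM in the naive and 199 CPM in the infected library. Cst3, abundant in myeloid cells, was at 105 and 167 CPM. The median marker of the B cell list was at only 0.369 and 0.238 CPM, and that of the myeloid list at 0.699 and 0.641 CPM. Ighm and Cst3 are therefore no measure of such cells. Transcripts of 17 pancreatic acinar enzyme genes, a list drawn up after the clusters were seen, summed to 11.5 CPM in the naive and 199 CPM in the infected library. Xist was read in both libraries at 403 and 619 CPM, and the Y-linked genes Ddx3y, Uty and Eif2s3y had 0 UMIs in both. Y-linked Kdm5d had 0 naive and 6 infected UMIs.

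**Figure D1:**
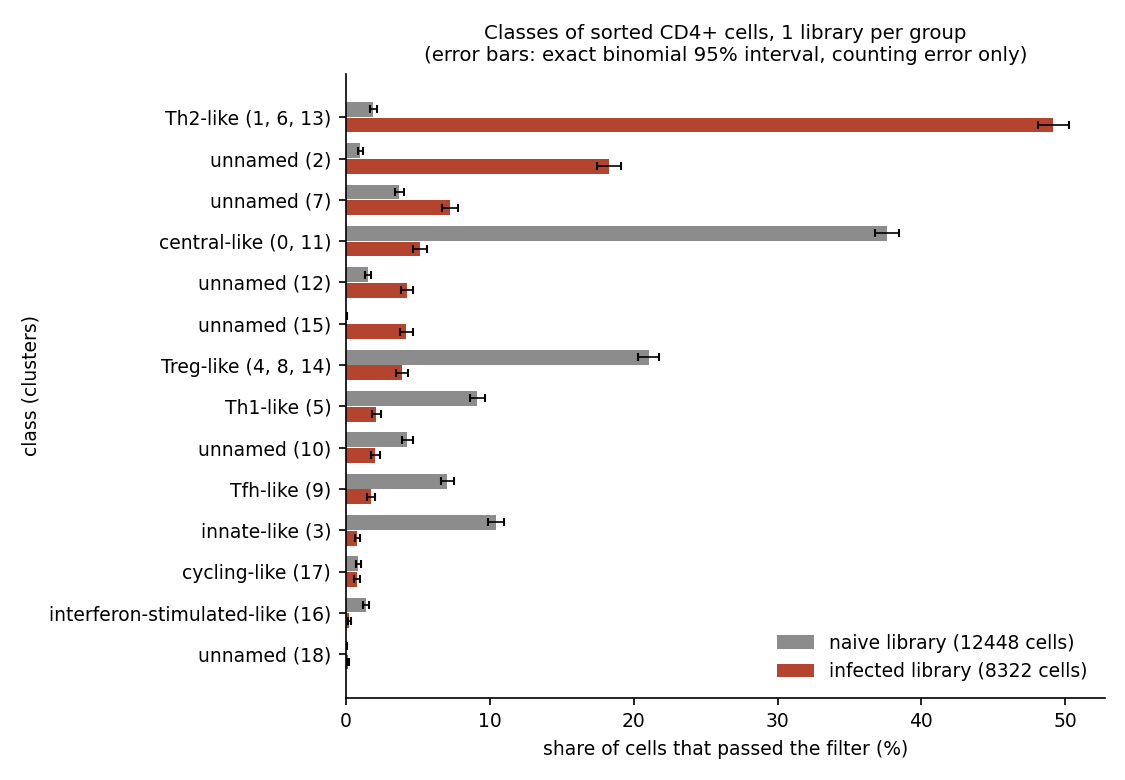
Share of passing cells in each class or unnamed cluster (%), in the naive (n = 12448 cells) and infected (n = 8322 cells) library, with exact 95% intervals. Th2-like cells made up 1.89% of naive and 49.1% of infected cells, and central-like cells 37.6% and 5.17%.

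The comparison of cell types asked which kinds of CD4+ T cell the lamina propria held with and without the worm. Type 2 helper (Th2) cells, which make IL-4, IL-5 and IL-13 and drive the gut's response to worms, formed the main population of the infected library and a rare one of the naive library. Naive or central memory T cells, which circulate through lymphoid tissue and express Ccr7, formed the main population of the naive library. Regulatory T cells (Treg), Th1 cells, follicular helper cells (Tfh) and innate-like T cells each held a smaller share of the infected library. All shares of a library add up to the whole, so the larger Th2-like share by itself lowers the shares of other classes. A smaller share is therefore not by itself a sign of fewer such cells in the tissue. Th2 and HIF pathway genes were kept out of the clustering, but Th2 markers named the clusters and so helped to set the size of the Th2-like class.

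Th2-like cells were 235 of the naive cells (1.89%, 1.66 to 2.14) and 4090 of the infected cells (49.1%, 48.1 to 50.2), 26.0-fold more. Cluster 1 held most of them in both libraries, with 133 naive and 2538 infected cells. Cluster 6 added 99 and 1013 cells. Cluster 13 added 3 and 539 cells, and a cluster mostly of 1 library may be that library rather than a cell type. Defined instead as cells outside the innate-like cluster with a UMI of Il4, Il5 or Il13, Th2-like cells were 8.84% of all passing naive and 61.7% of all passing infected cells. These cells were called without thinning, so both shares depend on depth, and infected cells were deeper. Cluster 2, which had too few marker genes for a name under thresholds set after the data were seen, held 0.980% of naive cells (0.815 to 1.17) and 18.3% of infected cells (17.5 to 19.1). With cluster 2 counted in, Th2-like cells were 2.87% and 67.4%. Cluster 15, left unnamed because pancreatic genes led it, held 0.0402% of naive and 4.21% of infected cells (3.78 to 4.66).

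Central-like cells were 37.6% of naive (36.8 to 38.5) and 5.17% of infected cells (4.70 to 5.66), 7.28-fold fewer, and most lay in cluster 0 in both libraries (4115 and 364 cells). Treg-like cells were 21.04% (20.3 to 21.8) and 3.91% (3.50 to 4.34). Cluster 4 was the main Treg-like cluster of both libraries (1156 and 203 cells), and cluster 8 held a further 985 naive and 65 infected cells. Th1-like cells were 9.13% (8.63 to 9.65) and 2.10% (1.81 to 2.43), and leaving out the cells with the highest doublet scores moved the infected share to 3.62%. Tfh-like cells were 7.05% (6.60 to 7.51) and 1.74% (1.47 to 2.05). Innate-like T cells, which express Zbtb16, were 10.4% (9.90 to 10.99) and 0.805% (0.624 to 1.02), the widest gap of a named class as a fold after Th2-like cells. Cycling cells differed least, at 0.860% (0.705 to 1.04) and 0.769% (0.593 to 0.981). These are shares of sorted live CD4+ cells that passed the UMI filter, and the infected library was deeper per cell and lost a larger share of its barcodes. In barcodes that failed the filters Ccr7 was at 992 CPM (naive) and 997 CPM (infected), against 477 and 63.1 CPM in passing cells. Gata3 was at 89.5 and 181 CPM in them, against 195 and 751 CPM in passing cells. The filter may thus lower the infected central-like share and raise the Th2-like share. With 200 genes and no UMI minimum Th2-like cells were 1.61% and 36.0%.

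The expression comparison asked which genes differed between the CD4+ T cells of both libraries, with the innate-like cluster set aside, over 11149 naive cells with 51472571 UMIs and 8255 infected cells with 48333048 UMIs. The infected library held more of the genes that Th2 cells use to fight worms, the cytokine genes Il4, Il5 and Il13 among them. It also held more Epas1, which encodes the hypoxia-inducible factor HIF-2α that the series is about, while Hif1a, which encodes HIF-1α, was slightly lower. Genes of Treg, Th1, Tfh and circulating T cells were lower in the infected library. These totals mix the makeup of each library with the level per cell, and the following comparisons take both apart.

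Epas1 (ENSMUSG00000024140, GRCm38 chromosome 17, 86753700 to 86833410, plus strand) was read 3823 times in the naive and 34310 times in the infected library. Its level was 74.3 CPM and 710 CPM, 9.56-fold higher in the infected library (log2 ratio 3.26, 3.21 to 3.31). Hif1a (ENSMUSG00000021109, chromosome 12, 73901375 to 73947530, plus strand) was at 323 and 269 CPM (-0.26, -0.29 to -0.23), and its exons overlap those of Gm49321, so reads of either gene cannot always be assigned. The other genes of the oxygen-sensing pathway differed less than Epas1. Egln3, a prolyl hydroxylase that marks HIF proteins for breakdown, was at 0.64 (0.54 to 0.75), Egln1 at 0.34 (0.25 to 0.44) and Egln2 at -0.13 (-0.22 to -0.04). Hif1an, which hydroxylates HIF at an asparagine, was at -0.47 (-0.60 to -0.35), the HIF partner Arnt at -0.11 (-0.20 to -0.02) and Vhl, which ubiquitinates HIF, at -0.06 (-0.21 to 0.10). Arnt2 (-0.45, -0.89 to -0.01) and Hif3a (0.43, -0.50 to 1.38) were rare, and Hif3a turned to -0.19 with the innate-like cluster kept in. The median of the 10 HIF pathway genes was -0.08, at percentile 13.95 of 10000 random lists matched on expression, with 2 genes at least 1.5-fold higher and 0 at least 1.5-fold lower.

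Il13 (ENSMUSG00000020383, chromosome 11, 53631324 to 53634702, minus strand) was at 2.37 CPM in the naive and 114 CPM in the infected library, 48.3-fold higher (5.59, 5.33 to 5.86). Il5 (ENSMUSG00000036117, chromosome 11, 53720794 to 53725106, plus strand) was 17.05-fold higher (4.09, 3.85 to 4.35). Il4 (ENSMUSG00000000869, chromosome 11, 53602982 to 53618669, minus strand) was at 60.2 and 309 CPM, 5.13-fold higher (2.36, 2.30 to 2.42). Gata3 (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034, minus strand), the master regulator of Th2 cells, was 3.79-fold higher at 199 and 754 CPM (1.92, 1.89 to 1.95), and its exons overlap those of 9230102O04Rik. The median of 12 measured Th2 cytokine and effector genes was 3.67 (percentile 100), with 10 genes at least 1.5-fold higher and 2 lower. Il6 was at 0.913 and 44.8 CPM (5.62, 5.199 to 6.06), Csf2 at 5.54 and 104 CPM (4.23, 4.06 to 4.41), and Il9 had 0 UMIs against 106, at least 37.6-fold higher by the floor of 3 UMIs over the naive total. The 2 lower genes were Il10 (-1.99) and Il21 (-1.79), which Treg and Tfh cells also make. With the innate-like cluster kept in, Csf2 was at 3.16, and the mean of the list in place of its median was 2.92.

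Th2 regulators and receptors had a median of 0.65 (percentile 100; 11 of 22 genes higher and 4 lower). Pparg, a lipid-sensing nuclear receptor, was at 1.83 and 69.0 CPM (5.24), the IL-33 receptor gene Il1rl1 at 9.97 and 119 CPM (3.58), the leukotriene receptor gene Cysltr1 at 8.98 and 88.2 CPM (3.30) and the IL-25 receptor gene Il17rb at 25.7 and 236 CPM (3.20). Lipid handling genes had a median of 0.71 (percentile 100; 8 of 15 higher and 1 lower), among them Mgll (4.23) and Dgat1 (1.15), with Dgat2 lower (-1.84). Neuro-immune genes had a median of 0.48 (percentile 99.4; 4 of 9 higher and 3 lower). The neuromedin U receptor gene Nmur1 was at 16.6 and 193 CPM (3.54), the neuropeptide gene Calca at 5.25 and 74.8 CPM (3.83) and Vipr2 at 4.27, while Vipr1, for the other receptor of the same peptide, was at -2.69.

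HIF target genes had a median of 0.34 (percentile 99.8; 8 of 27 higher and 2 lower). Ero1l was at 51.9 and 218 CPM (2.07), Ddit4 at 77.4 and 276 CPM (1.84) and P4ha2 at 1.59, whereas Pdk1, which turns pyruvate away from mitochondria, was lower at 54.5 and 21.2 CPM (-1.36). Glycolysis genes had a median of 0.24 (percentile 98.0; 5 of 17 higher and 0 lower), with Hk2 at 1.66, Tpi1 at 1.06, Slc2a1 at 0.75 and Gapdh at 349 and 570 CPM (0.71). Oxidative phosphorylation genes had a median of -0.02 (percentile 43.8) and 0 of 22 reached 1.5-fold, the most different being Uqcrfs1 (-0.33), Sdhb (-0.30) and Ndufa4 (-0.27).

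Treg genes had a median of -1.26 (percentile 0; 1 of 14 higher and 10 lower). Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand), their master regulator, was at 193 and 42.1 CPM (-2.20, -2.26 to -2.13), and its exons overlap those of Flicr. Ikzf2 was at 215 and 60.4 CPM (-1.83) and Lrrc32 at -1.85. Th1 genes had a median of -1.08 (percentile 0; 2 of 12 higher and 9 lower), with Il12rb2 at -2.24, Ccl5 at 288 and 66.7 CPM (-2.11), Eomes at -1.72 and Ifng, whose exons overlap those of Gm49751, at 43.2 and 19.0 CPM (-1.19). Tbx21 (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331, minus strand), the regulator of Th1 cells, was instead at 37.1 and 45.3 CPM (0.29, 0.20 to 0.38). Its direction depended on the cells counted, with -0.54 when the innate-like cluster was kept and -0.9999 when every unnamed cluster, cluster 2 included, was left out. Th17 genes had a median of -0.40 (percentile 0.44; 4 of 12 higher and 5 lower), with Ccr6 at -2.56, Il23r at -2.21 and Il17a at 19.1 and 12.8 CPM (-0.58). The Th17 median was 0.052 when each cell had the same weight, and the oxidative phosphorylation median was then 0.016.

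Tfh genes were lower in 9 of 9 cases (median -1.48, percentile 0), among them Sostdc1 (-2.09), Il21, Cxcr5 (-1.69) and Ascl2 (-1.64). Genes of circulating T cells were lower in 8 of 8 cases (median -2.43, percentile 0). Ccr7 (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077, minus strand), which guides T cells to lymph nodes, was at 525 and 63.4 CPM (-3.05), and S1pr1 and Lef1 were at -2.68 and -2.45. Tissue residency genes had a median of 0.48 (percentile 100; 7 of 16 higher and 3 lower), with Cxcr6 at 89.3 and 294 CPM (1.72), Rgs1 at 875 and 2089 CPM (1.26), Gpr55 at -2.47 and Gpr15 at -1.55. Inhibitory receptor genes had a median of -0.94 (percentile 0; 1 of 10 higher and 8 lower), among them Ctla4 at 646 and 245 CPM (-1.40), Tigit (-1.60), Tox (-1.35) and Btla (-1.26). Giving each cell the same weight moved Ccr7 to -2.40, Ccr6 to -1.58, Cxcr5 to -0.91, Il21 to -0.85 and Tigit to -0.98. It also moved Sostdc1 to -1.10 and Ascl2 to -0.72. Keeping the innate-like cluster moved Cxcr6 to 0.98.

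Interferon response genes had a median of -0.57 (percentile 0.01; 1 of 13 higher and 6 lower), with Ifit3 at -2.57, Ifit1 at -1.92 and Oasl2 at -1.63, while Ly6a was at 168 and 705 CPM (2.07). Cell cycle genes had a median of -0.41 (percentile 0.18; 1 of 14 higher and 6 lower), with Stmn1, whose exons overlap those of Gm23634, at -1.60, Ccnb2 at -1.45 and Pclaf at -0.997. Mki67 was level at 16.2 and 15.5 CPM (-0.06, -0.20 to 0.09), and when each cell had the same weight Ccnb2 was at -0.35, Pclaf at -0.17 and Birc5 turned from -0.87 to 0.18. Genes induced by handling and early activation had a median of 0.61 (percentile 100; 8 of 16 higher and 0 lower). They included the heat shock genes Hspa1b at 89.4 and 516 CPM (2.53) and Hspa1a at 61.2 and 341 CPM (2.48), near-identical copies whose reads cannot be assigned with certainty, and Ier3 (2.18) and Atf3 (1.99).

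The 12 genes with the highest ratios were rare in the naive library, so that most of their ratios have wide intervals. Alox5 (ENSMUSG00000025701, chromosome 6, 116410077 to 116461178, minus strand), which makes leukotrienes and is a leading gene of cluster 13, had 0 naive and 648 infected UMIs, at least 230-fold higher. Ccl1 (ENSMUSG00000020702, chromosome 11, 82176657 to 82305690, minus strand), the ligand of CCR8, was at 1.94 and 209 CPM, 107-fold higher (6.75, 6.46 to 7.05). Hs3st1, a heparan sulfate sulfotransferase gene, was at 2.02 and 161 CPM (6.31, 6.04 to 6.61). Fez1 (1 against 381 UMIs, 8.66, 6.18 to 13.97), Tarm1 (7.31, 5.75 to 9.59), Cyp11a1 (7.28, 5.41 to 10.33), which makes steroids and whose exons overlap those of Gm17322, Soga1 (6.79), Spink2 (6.53), Car8 (6.43), Gfra2 (6.34), Cntn1 (6.30) and the pancreatic gene Cpa1 (6.15) made up the rest. The lowest ratios were those of Zbtb16 at 9.11 and 0.186 CPM (-5.61, -6.75 to -4.68), the regulator of innate-like T cells that remained after their cluster was set aside, and Hdac9 (117 against 3 UMIs, -5.19, -7.49 to -3.61). Snord35a (-4.62), Lbp (-3.67), Amigo2 (-3.48), Pid1 (-3.46), Cables1 (-3.30), Gprc5b (-3.18), Ednrb (-3.17), Sox4 (-3.17), Bach2it1 (-3.13) and Arhgap29 (-3.06) followed. Zbtb16 was at -4.41 with the innate-like cluster kept in, and Pid1 at -2.27 with equal weight per cell.

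**Figure D2:**
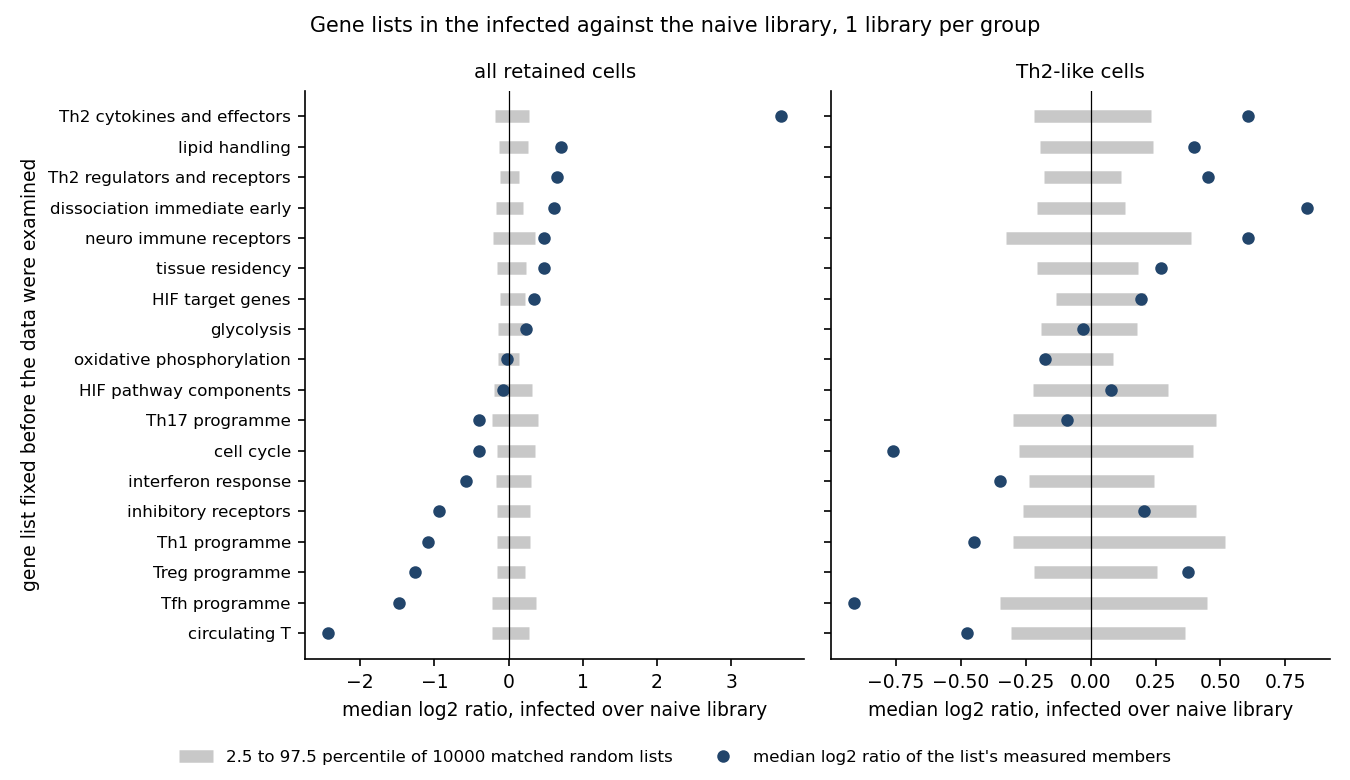
Median log2 ratio (infected over naive) of each gene list fixed in advance, in the whole library and in Th2-like cells, beside the central 95% of 10000 random lists matched on expression. Th2 cytokine genes had the highest whole-library median at 3.67 and circulating T cell genes the lowest at -2.43.

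The makeup of the libraries by class was then taken out by weighting the infected level of each class by that class's share of naive UMIs. Shifts between clusters inside a class were not taken out. Epas1 stayed higher in the infected library, at 1.31 in place of 3.26. Il13 was at 2.49, Il5 at 1.12, Gata3 at 0.58 and Il4 at 0.37. The Th2 cytokine list was at 0.96, the Th2 regulator list at 0.27 and the lipid list at 0.26. The HIF target list turned from 0.34 to -0.016. The circulating T cell list was at -0.057 in place of -2.43. The Tfh list moved from -1.48 to -0.25 and the Th1 list from -1.08 to -0.14. Foxp3 turned from -2.20 to 0.076, Il10 from -1.99 to 0.23, Ikzf2 to 0.048 and the Treg list to 0.26. Hk2 turned to -0.30, P4ha2 to -0.56, Pdk1 to 0.037 and Tbx21 to -0.35. This weighting moved 96 of 124 whole-library values by more than 1.5-fold.

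The comparison of Epas1 between cell types asked whether Th2 cells differ from other CD4+ T cells in HIF-2α expression and whether those other cells also differed between libraries. Epas1 was highest in Th2-like cells among the named classes of the naive library, and central-like cells had the least. In the infected library it was higher in Th2-like cells and also in Treg-like, Tfh-like, Th1-like, central-like and interferon-stimulated cells, where the ratio was larger. Epas1 was not higher in innate-like or cycling cells. Hif1a had another distribution, and among the named classes it was highest in Tfh-like and Treg-like cells.

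In the naive library Epas1 was at 626 CPM in Th2-like cells and 59.0 CPM in the other retained cells, 10.6-fold higher. The log2 ratio of Th2-like over other cells was 3.41 (3.30 to 3.52), and 2.38 with Th2-like cells defined by a cytokine UMI. In the infected library Epas1 was at 883 and 469 CPM, 1.88-fold higher (log2 ratio 0.91, 0.88 to 0.95). That infected log2 ratio was 2.57 when the unnamed clusters were left out, since cluster 2, cluster 12 and cluster 15 had 627, 1441 and 838 CPM. Th2-like cells held 22.7% of the Epas1 UMIs of the naive and 72.3% of those of the infected library. Treg-like cells were at 99.0 CPM (93.8 to 104) in the naive and 236 CPM (215 to 258) in the infected library, 2.38-fold higher. Tfh-like cells were at 37.7 (32.0 to 44.1) and 185 CPM (158 to 215), 4.90-fold higher, and Th1-like cells at 82.1 (74.1 to 90.7) and 234 CPM (203 to 267), 2.85-fold higher. Central-like cells were at 10.1 (8.80 to 11.6) and 27.8 CPM (21.6 to 35.2), 2.74-fold higher from a low level. Innate-like T cells were at 104 (96.0 to 114) and 90.8 CPM (60.4 to 131), and cycling cells at 106 (83.2 to 133) and 79.2 CPM (50.8 to 118), with overlapping intervals. Interferon-stimulated cells were at 71.9 (55.1 to 92.2) and 425 CPM (299 to 586), the latter from 18 cells. Within clusters the direction held in the main Treg-like clusters, with cluster 4 at 153 (143 to 164) and 311 CPM (282 to 343) and cluster 8 at 69.6 (63.3 to 76.4) and 124 CPM (91.9 to 163). Cluster 14 was at 39.7 (31.3 to 49.7) and 67.5 CPM (42.3 to 102), with overlapping intervals. Cluster 4 held 1156 of 2619 naive and 203 of 325 infected Treg-like cells, so part of the 2.38-fold is a change in the mix of clusters. Hif1a was at 745 and 529 CPM in Tfh-like, 513 and 452 CPM in Treg-like and 221 and 253 CPM in Th2-like cells. Its log2 ratio of Th2-like over other cells was -0.56 in the naive and -0.21 in the infected library, and that of Egln3 was 0.94 and 0.59.

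**Figure D3:**
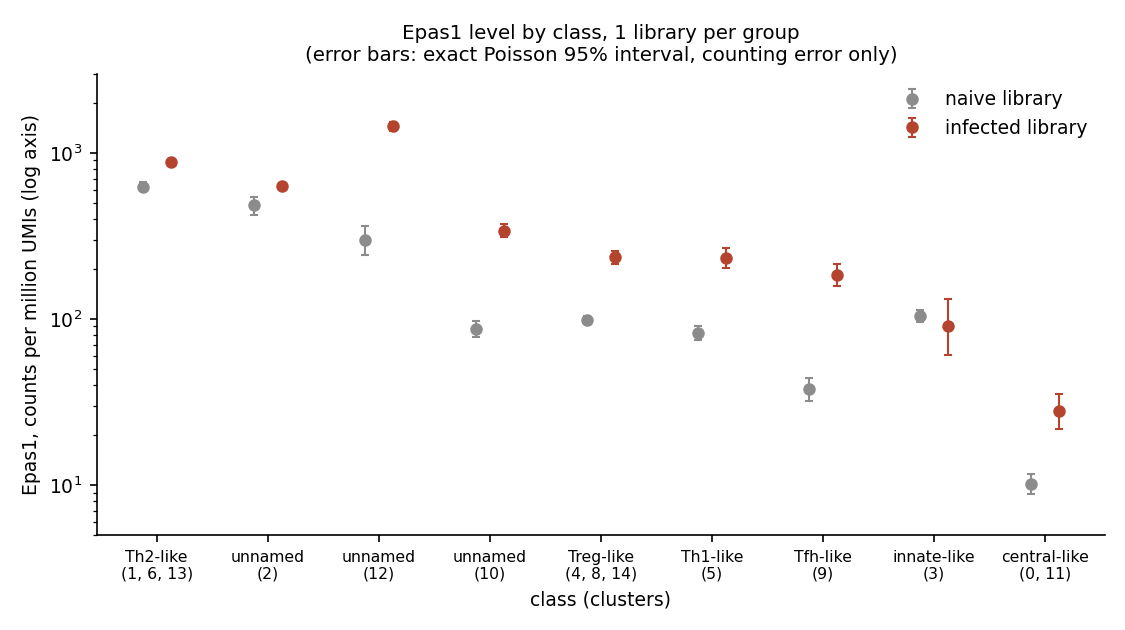
Epas1 level (CPM) in selected classes of the naive and infected library, with exact 95% intervals on the summed UMIs. Shown are Th2-like, Treg-like, Th1-like, Tfh-like, central-like and innate-like cells and clusters 2, 10 and 12. Th2-like cells were at 626 and 883 CPM, and Tfh-like cells at 37.7 and 185 CPM.

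The comparison within Th2-like cells asked how such cells of an infected gut differ from the few found in a naive one. Gata3, Il4 and Il5 differed by less than 1.5-fold between them. The infected cells had more Il13, Csf2 and Il1rl1, the receptor gene for the alarmin IL-33, and moderately more Epas1. They also had more heat shock transcripts and less of Ccr7 and Ccr4, which encode chemokine receptors. The naive side rests on 235 cells with 1387282 UMIs and the infected side on 4090 cells with 28110629 UMIs, with medians of 5714 and 6394 UMIs per cell. Of the infected cells 539 came from cluster 13, which had 3 naive cells and whose leading genes include Il1rl1, Igfbp7, Il1r2, Irs2 and Alox5.

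Epas1 was at 626 CPM (585 to 669) in the naive and 883 CPM (872 to 894) in the infected Th2-like cells, 1.41-fold higher (0.50, 0.40 to 0.59). Gata3 was at 833 and 917 CPM (0.14, 0.05 to 0.23), Il4 at 479 and 386 CPM (-0.31, -0.42 to -0.20) and Il5 at 59.8 and 55.3 CPM (-0.11, -0.43 to 0.22). Il13 was at 69.9 and 170 CPM, 2.43-fold higher (1.28, 0.99 to 1.59). Hif1a was at 0.19 (0.03 to 0.36). Among the other HIF pathway genes Egln1 (0.10, -0.28 to 0.50), Egln2 (0.43, -0.04 to 0.95), Egln3 (-0.04, -0.41 to 0.35), Vhl (0.08, -0.64 to 0.90), Hif1an (-0.39, -0.94 to 0.20), Arnt (-0.15, -0.53 to 0.26) and Hif3a (1 against 12 UMIs, -0.76, -3.51 to 4.66) had intervals that span 0. Arnt2 had 0 against 36 UMIs, too few for a ratio. The median of 9 measured HIF pathway genes was 0.08 (percentile 69.5; 0 higher and 0 lower by 1.5-fold). In cells defined by a UMI of Il4, Il5 or Il13 instead, Epas1 was at 1.77, Il13 at 3.23, Il5 at 1.73, Gata3 at 1.07 and Hif1a at -0.86. The naive cells of this definition include other types. Th2-like cells held only 21.4% of the naive Il4 UMIs of retained cells, and Tfh-like cluster 9 read Il4 at 234 CPM over both libraries. The larger ratios therefore also reflect a different mix of cell types on the naive side.

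The Th2 cytokine list had a median of 0.61 (percentile 99.98; 6 of 11 higher and 1 lower), with Csf2 at 12.3 and 96.5 CPM (2.98, 2.30 to 3.76), Lif at 1.64 and Il6 at 24.5 and 65.3 CPM (1.41). The Th2 regulator list had a median of 0.45 (percentile 100; 8 of 22 higher and 1 lower). Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415, plus strand) was at 19.5 and 154 CPM (2.99, 2.44 to 3.59), the chemokine receptor gene Ccr8 at 30.3 and 191 CPM (2.66), Il7r at 275 and 747 CPM (1.44) and Ccr4 at 148 and 26.0 CPM (-2.52, -2.74 to -2.29). HIF target genes had a median of 0.19 (percentile 96.7; 6 of 24 higher and 1 lower), with Ndrg1 at 0 against 394 UMIs, at least 6.48-fold higher, Ddit4 at 95.2 and 291 CPM (1.61), Mxi1 at 1.15 and P4ha2 at -1.10. Glycolysis genes had a median of -0.03 (percentile 45.4; 2 of 17 higher and 1 lower), with the glucose transporter genes Slc2a3 and Slc2a1 at 1.41 and 1.02 and Hk2 at -0.72. Oxidative phosphorylation genes had a median of -0.18 (percentile 2.67; 0 of 22 higher and 1 lower), with Uqcrfs1 at -0.60, Ndufa4 at 412 and 291 CPM (-0.50) and Atp5c1 at -0.43. Lipid handling genes had a median of 0.40 (percentile 99.85; 5 of 14 higher and 1 lower), with Pparg at 40.4 and 93.4 CPM (1.21), Dgat1 at 1.14 and Mgll at 0 against 175 UMIs, at least 2.88-fold higher.

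Genes of other programmes differed in both directions. Treg genes had a median of 0.37 (percentile 99.6; 5 of 13 higher and 3 lower), with Itgae at 2.12, Ikzf2 at -1.69, Izumo1r at -1.58 and Ikzf4 at 0 against 152 UMIs, a log2 ratio of at least 1.32. Th1 genes had a median of -0.45 (percentile 0.54; 3 of 9 higher and 3 lower), with Ccl5 at -1.95, Cxcr3 at -1.10, Il18rap at 1.34 and Gzmb at 3 against 167 UMIs (1.46, -0.11 to 3.75). Th17 genes had a median of -0.09 (percentile 20.3; 4 of 9 higher and 2 lower), with Il1r1 at 0 against 293 UMIs, at least 4.82-fold higher, Il17a at 1.29 and Tmem176b at -1.95. Tfh genes had a median of -0.91 (percentile 0.02; 1 of 5 higher and 4 lower), with Tox2 at -1.71, Slamf6 at -1.14, Bcl6 at -0.91 and Pdcd1 at 1.44. The regulators Foxp3 and Tbx21 were at -1.08 and -1.04, and Ifng (-0.45, -1.63 to 1.03) had an interval that spans 0. Circulating T cell genes had a median of -0.47 (percentile 0.24; 1 of 8 higher and 3 lower), with Ccr7 at 41.8 and 5.41 CPM (-2.95), S1pr1 at -1.06, Lef1 at -0.51 and Satb1, whose exons overlap those of Gm36931, at 1.94. Residency genes had a median of 0.27 (percentile 99.55; 4 of 14 higher and 2 lower), with Cxcr6 at 0.95, Cd69 at 0.75 and Itga4 at -1.05.

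Inhibitory receptor genes had a median of 0.21 (percentile 82.6; 5 of 10 higher and 3 lower), with Entpd1 at 2 against 379 UMIs (3.23, 1.36 to 6.28), Havcr2 at 2 against 189 (2.22, 0.35 to 5.28) and Lag3 at 1.31. Genes of handling and early activation had a median of 0.83 (percentile 100; 10 of 16 higher and 0 lower), with Hspa1a at 15.1 and 277 CPM (4.19, 3.58 to 4.89), Hspa1b at 3.31 (2.94 to 3.70), Atf3 at 2.17 and Jun at 1.69. Interferon response genes had a median of -0.35 (percentile 0.29; 2 of 12 higher and 5 lower), with Ifi27l2a at 322 and 64.7 CPM (-2.32), Gbp2 at -1.42 and Ly6a at 1.73. Cell cycle genes had a median of -0.76 (percentile 0; 0 of 9 higher and 6 lower), with Mcm5 at -1.27, Top2a, whose exons overlap those of Gm23451, at -1.06, Mcm3 at -0.76 and Mki67 at -0.63 (-1.15 to -0.08). Neuro-immune genes had a median of 0.61 (percentile 99.6; 4 of 7 higher and 1 lower), with Vipr2 at 1.97, Calcrl at 0.79 and Ramp3 at 0.67. That median is the ratio of Calca (60.6 and 92.2 CPM), which is also the median of the Th2 cytokine list.

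Most of the 12 highest ratios belonged to genes nearly unread in the naive Th2-like cells. Penk (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819, minus strand), the precursor of enkephalin peptides, had 1 against 1133 UMIs (5.81, 3.32 to 11.11), and Cxcl2, a neutrophil attractant, had 2 against 1674 (5.37, 3.51 to 8.42). Ccl1 was at 3.68 (3.18 to 4.24). Irs2 (1 against 580 UMIs, 4.84), Igfbp7 (2 against 730, 4.17) and Il1r2 (0 against 1343, at least 22.1-fold higher) were among the leading genes of cluster 13. Hspa1a, AA467197 (3.88), Fez1 (3.86), Srgap3 (3.62), Ifitm10 (3.57) and Jup (3.38) completed the 12, and the exons of AA467197 and Ifitm10 overlap those of Mir147 and Gm49369. The lowest included Ccr7, Spry1 (-2.87), Lrig1 (-2.77), Ccr4, Cd9 (-2.37), Ifi27l2a, Rnf43 (-2.15), Myo6 (-2.09), Cybb (-1.96), Tmem176b and Ccl5. The choice of cells decided several of these values, and the naive cells picked by a cytokine UMI include other types, as given above. The definition by cytokine UMIs moved 64 of 117 values by more than 1.5-fold, with Penk at 0.65, Irs2 at 1.40, Il1r2 at 2.90, Cxcl2 at 2.68, Ccl1 at 5.201 and Hspa1a at 2.76. It turned the Treg list to -1.22, Itgae to -0.72, Pdcd1 to -1.98, Lag3 to -1.24, Entpd1 to -0.18, Hk2 to 0.52 and P4ha2 to 0.44, and moved the inhibitory receptor list to -1.90, the Th1 list to -2.13, the Tfh list to -2.88 and the circulating list to -2.61. Gzmb was then at -2.13, Egln2 at -0.33, Il5 at 1.73 and Il1r1 at 0.13. Cxcl2 was at 1.41 with cluster 15 counted in, Csf2 at 2.07 with cluster 2 counted in, and the circulating list at -1.78 without the cells of highest doublet score.

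The last comparison asked how many cells carried each transcript, since a level can come from few or many cells. A larger share of infected than of naive cells had an Epas1, Gata3, Il4, Il5 or Il13 UMI, and a smaller share had a Foxp3 UMI. Each cell was thinned to 2000 UMIs so that depth did not differ, and shallower cells were left out (1229 naive and 962 infected). Central-like cells, which should lack Th2 cytokines, gave the background, with medians of 4035 and 5485 UMIs before thinning.

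**Figure D4:**
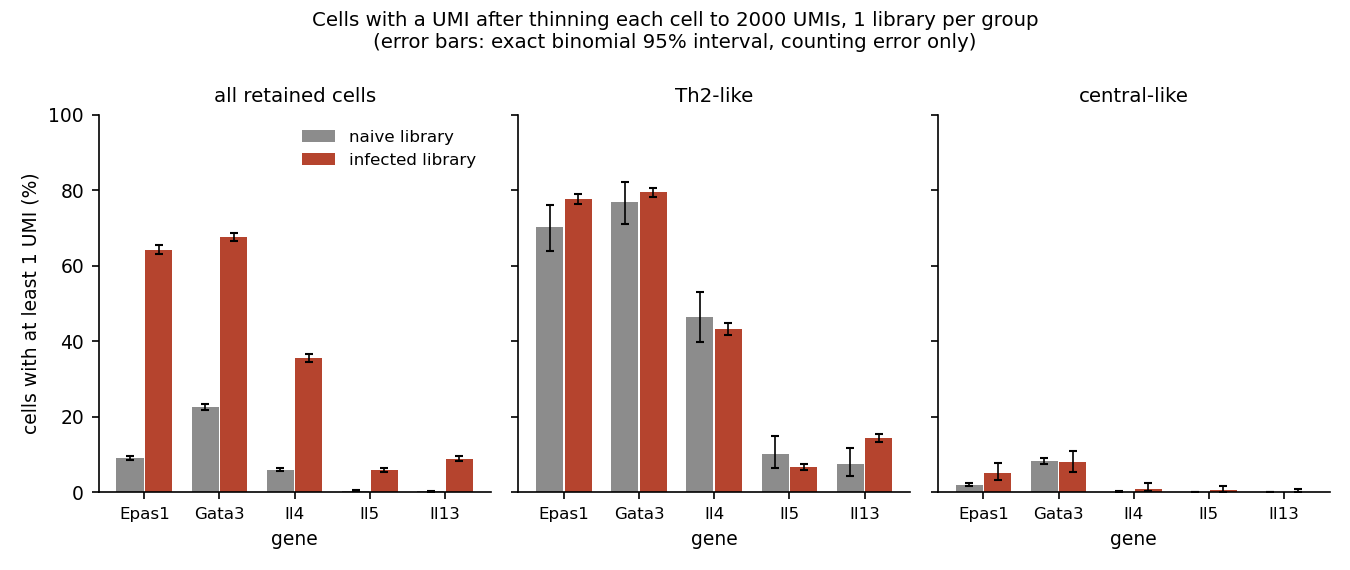
Share of retained cells (%) with at least 1 UMI of each gene after thinning every cell to 2000 UMIs, in the naive (n = 9920 cells) and infected (n = 7293 cells) library, with exact 95% intervals. Epas1 was read in 9.09% of naive and 64.3% of infected cells, and Il13 in 0.292% and 8.90%.

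Epas1 was read in 9.09% of 9920 naive cells (8.53 to 9.68) and 64.3% of 7293 infected cells (63.2 to 65.4), against 2.05% and 5.198% of central-like cells. Without thinning these were 16.1% and 76.9%. Il13 was read in 0.292% (0.196 to 0.420) and 8.90% (8.26 to 9.58), and in 0 of 4436 naive and 0 of 404 infected central-like cells, which at 3 cells of the total allows shares of cells with a UMI of up to 0.0676% and 0.743%. The Il13 share of infected cells was 16.1% without thinning and 4.93% at 1000 UMIs. Il5 was read in 0.373% (0.263 to 0.514) and 5.90%, or 0.727% and 11.9% without thinning, with 0 of 4436 and 2 of 404 central-like cells. Il4 was read in 5.99% (5.53 to 6.47) and 35.6% (34.5 to 36.7), or 9.499% and 57.3% without thinning, against 0.203% and 0.990% of central-like cells. The innate-like cluster, which is not counted here, also read Il4, at 262 CPM over both libraries. Gata3 was read in 22.6% (21.7 to 23.4) and 67.7%, or 35.0% and 79.7% without thinning, and in 8.34% and 7.92% of central-like cells. Foxp3 was read in 17.9% and 4.42%, or 23.5% and 6.40% without thinning, against 1.24% and 0.743% of central-like cells. Hif1a was read in 37.9% and 37.1%, or 57.1% and 66.3% without thinning, and in 19.9% and 19.6% of central-like cells. Among Th2-like cells, 226 naive and 4010 infected, the thinned shares were 70.4% (63.9 to 76.2) and 77.7% (76.3 to 78.9) for Epas1, 46.5% and 43.3% for Il4 and 7.52% (4.44 to 11.8) and 14.3% (13.3 to 15.5) for Il13. Rarer transcripts were read as follows. Tbx21 was read in 5.65% (5.199 to 6.12) of naive and 8.49% (7.86 to 9.15) of infected cells, or 9.93% and 15.7% without thinning, against 0.293% and 0.248% of central-like cells. That order depended on the cells counted, since the naive share was 10.7% with the innate-like cluster kept and the infected share 2.55% without the unnamed clusters. Ifng was read in 4.73% (4.32 to 5.16) and 2.24% (1.91 to 2.60), or 7.51% and 3.83% without thinning, against 0.113% and 0.248% of central-like cells. Il17a was read in 0.454% (0.331 to 0.607) and 0.439% (0.3003 to 0.619), with 2 of 4436 and 1 of 404 central-like cells. Mki67 was read in 1.83% and 2.73%, or 3.82% and 7.01% without thinning, with 6 of 4436 and 0 of 404 central-like cells, the last allowing up to 0.743% with a UMI by the same limit. Epas1 was read in 14.7% and 26.7% of Treg-like, 5.95% and 20.3% of Tfh-like and 11.6% and 33.9% of Th1-like cells.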

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

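The tests of free Epas1 RNA, of Th2-like RNA as the whole of the Epas1 excess, of infection raising Epas1, of both pancreatic explanations at equal depth and of the Hspa1 copies were chosen after the results were seen, and the other tests were chosen before.

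In Th2-like cells the oxidative phosphorylation list had a median log2 ratio of -0.18, opposite to 0.07 in Treg-like cells. The list of handling and early activation genes had a median of 0.83 in Th2-like against -0.42 in central-like cells. The neuro-immune list had a median of 0.61 (0.30 to 0.76, 7 genes) in Th2-like against -0.21 (-0.40 to -0.0011, 5 genes) in central-like cells. Its Th2-like median is the ratio of 1 gene, Calca, which is also the median of the Th2 cytokine list. These are opposite directions between cell types under the same contrast. The differences for the oxidative phosphorylation and neuro-immune lists were not tested. The 17 pancreatic enzyme genes, which are not expected in T cells, summed to 199 CPM in the infected and 11.5 CPM in the naive library. Signals also appeared in barcodes that failed the filters, which the comparisons do not use, where Epas1 was at 190 CPM (172 to 209) in the infected and 39.6 CPM (31.4 to 49.2) in the naive library, and Il13 at 13.7 and 1.47 CPM.

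Epas1 was higher in the infected library in Treg-like, Tfh-like and Th1-like cells, by at least 2.38-fold per class. The Treg-like value includes a change in the mix of its clusters. Free Epas1 RNA would reach every droplet alike, but the smallest excess per cell among these classes, 0.888 UMIs in Th1-like cells (0.722 to 1.06), was 7.77 times the 0.114 UMIs of central-like cells (0.0775 to 0.154). Th2-like RNA or doublets as the whole cause would need as much of it for other Th2 genes as for Epas1. The median need of the other genes was at most 0.447 of the share that Epas1 needed. In Th1-like cells that median was 2.48% (1.04 to 3.41, 21 genes). Epas1 needed 17.2% (13.6 to 20.9) there, above the central 95% of single genes (-3.18 to 10.3). This argues against RNA of the Th2-like class as the whole cause in Th1-like cells. The other genes were picked for a low naive level in the class, a rule not applied to Epas1. RNA of cluster 2 was not tried. Its infected cells read Epas1 at 627 against 883 CPM in Th2-like cells, but Il13 at 23.3 against 170 CPM, so the test cannot decide on cluster 2. In Treg-like and Tfh-like cells Epas1 needed 15.5% and 16.7%. These lay inside the central 95% of single genes (0.988 to 23.8 and -0.844 to 17.3), so the median cannot decide the question there. In the test chosen before, Epas1 lay above the central 95% of those genes in 1 of 3 classes where all 3 were required. Th2-like RNA may thus make up part of the excess, and in Treg-like and Tfh-like cells the whole of it stays open. Higher Epas1 in the 3 classes through infection and a difference between the pools cannot be told apart, because infection and library are the same split.

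Transcripts of 17 pancreatic enzyme genes, a list drawn up after the clusters were seen that shares 0 genes with the other lists, were read in cells of the infected library, led by Clps and Ctrb1 at 38.5 and 30.9 CPM. Acinar cells are a candidate source as a hypothesis only, since sorting live CD4+ cells should remove them, and of the 17 genes Cela1 was left out of the tests at equal depth because it was read in naive Foxp3 cells at 10.4 CPM (8.69 to 12.3) and in naive Ccr7 cells at 0.745 CPM. At 2000 UMIs the share with such a UMI was 5.19% (3.38 to 7.56) in Ccr7 cells and 9.82% (8.999 to 10.7) in cytokine cells, a ratio of 0.528 that argues against free RNA at 1 level in every droplet, and it was 10.1% (7.01 to 13.95) in Foxp3 cells, a ratio of 1.03 to cytokine cells that argues against expression by cytokine cells alone. The test chosen before fell between its bounds, with cytokine cells 1.23 times as frequent among cells with at least 3 pancreatic UMIs (75.2% of 609 against 61.2% of 7713). In infected barcodes that failed the filters Ctrb1 was at 32.8 CPM (25.6 to 41.3, 72 UMIs in 2912 barcodes). In passing cells it was at 30.8 CPM (29.3 to 32.4, 1498 UMIs in 8322 cells). Free RNA at 1 level in every droplet would give a higher CPM in barcodes with few UMIs, which was not seen for this gene. Free RNA at an uneven level and expression by several kinds of T cell stay open and untested.

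Heat shock and immediate-early genes were higher in Th2-like cells of the infected library. Handling that acts on every class alike would raise them in central-like and Tfh-like cells too, but the higher of the medians there was -0.24 (-0.31 to -0.19, Tfh-like) against 0.83 (0.73 to 0.92) in Th2-like cells. Reads shifted between the near-identical Hspa1a and Hspa1b would leave their sum level, but the sum was 12.1-fold higher (9.72 to 15.2). Single genes did not follow the list, since Hspa1a was at 2.03 in Treg-like and 2.04 in Th1-like cells. Over all other retained cells Hspa1a was at 62.5 CPM in the naive and 431 CPM in the infected library, against 15.1 and 277 CPM in Th2-like cells. Hspa1b was at 90.7 and 637 CPM there, against 43.3 and 429 CPM. The heat shock difference was thus not confined to Th2-like cells. Handling that acts on some cell types more than on others may contribute, as may infection, and both stay open and untested.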

How the results depend on the processing

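The settings for doublet scores, cluster 2, cluster 15, pancreatic-led clusters and unnamed clusters, and the tests made with them, were chosen after the data were seen, and the other settings before.

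Counted over 10 main results and every alternative that applies to each, 103 values lay within the interval of the reported value, 34 lay outside it and 1 reversed. Of the other results 3179 lay within, 493 outside and 38 reversed. Some of those within a wide interval still differed by more than 1.5-fold or in sign, such as Aldoc within Th2-like cells, at 0.49 as reported and -0.53 as a mean over cells. A sign change counted as reversed where the reported interval excluded 0. Epas1 was higher in the infected library under every alternative, with a log2 ratio from 1.31 to 3.44 in the whole library and from 0.43 to 1.77 within Th2-like cells. The 1.77 is from cells defined by a cytokine UMI, whose naive side includes other cell types. The Th2 cytokine list ranged from 0.96 to 3.98 in the whole library, and the HIF target list within Th2-like cells from 0.11 to 0.36. Leiden resolutions of 0.6 and 1.5, 50 components, Th2 and HIF genes among the variable genes, and list members with at least 100 UMIs moved none of the main results to which each applies. Keeping called doublets is identical to the settings used, since no cell was removed. No paired analysis was possible because each group was 1 pooled library. The precision of the Th2-like comparison is limited by its 235 naive cells, and genes with a few naive UMIs have ratios known only within wide intervals. Where values moved or reversed the cause was not tested, except where the setting itself changes the cells or the weights.

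The whole-library Epas1 log2 ratio was 3.20 with median-of-ratios factors and 3.21 without ribosomal, mitochondrial and receptor genes. As a mean over cells Epas1 was 3.32, and its log2 ratio of Th2-like over other cells was 3.60 in the naive and 0.95 in the infected library. Birc5 then reversed to 0.18, the oxidative phosphorylation list to 0.016 and the Th17 list to 0.052. The mean over list members gave 2.92 for Th2 cytokines. The infected share of cells with an Il13 UMI was 4.93% at 1000 UMIs and 16.1% without thinning.

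At naive class shares Epas1 was 1.31, the Th2 cytokine list 0.96, and the HIF target list reversed to -0.016. Many genes of classes with unequal shares reversed too, by the construction of the weights. In the whole library these included Arnt2 (0.86), Atf3 (-0.093), Birc5 (0.13), Btla (0.11), Egln1 (-0.14), Eomes (1.14), Foxp3 (0.076), Gpr15 (0.40), Hk2 (-0.30), Ifit3 (0.012), Ikzf2 (0.048), Il10 (0.23), Lrrc32 (0.50), P4ha2 (-0.56), Pdk1 (0.037), Tbx21 (-0.35) and Tigit (0.10). The lists that reversed were Treg (0.26), inhibitory receptors (0.11), handling and early activation (-0.025) and interferon response (0.067).

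With every passing cell kept Epas1 was 3.19 and the Th2 cytokine list 3.50, and Tbx21 reversed to -0.54. With Th2-like cells defined by an Il4, Il5 or Il13 UMI outside the innate-like cluster, their share of all passing cells, without thinning, was 8.84% and 61.7%. Epas1 within them was 1.77, and its log2 ratio over other cells was 2.38 in the naive and 1.05 in the infected library. The genes that reversed within them were Entpd1 (-0.18), Hif1a (-0.86), Hk2 (0.52), Ikzf4 (-0.84), Itgae (-0.72), Lag3 (-1.24), P4ha2 (0.44), Pdcd1 (-1.98) and Satb1 (-0.032), and the Treg list reversed to -1.22.

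With cluster 2 counted as Th2-like the shares were 2.87% and 67.4%, and the infected Epas1 log2 ratio of Th2-like over other cells was 1.16. With cluster 15 counted in, the infected share was 53.4% and that log2 ratio 1.08, and without the pancreatic-led clusters it was 1.09. Without the unnamed clusters Epas1 was 3.44 in the whole library and the Il13 share was 11.4%. Its log2 ratio of Th2-like over other cells, for Epas1, was then 3.62 in the naive and 2.57 in the infected library. Tbx21 then reversed to -0.9999 and the oxidative phosphorylation list to 0.0071. At under 5% mitochondrial UMIs the infected Th2-like share was 51.2% and the infected Epas1 log2 ratio over other cells 1.02. Without the highest doublet scores the naive share was 2.21% and that log2 ratio 1.03. With 200 genes and no UMI minimum the shares were 1.61% and 36.0%, and that log2 ratio was 0.98.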

Other observations

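The tests of cluster 2 and of receptor segment use were chosen after the clusters were seen.

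The infected library held a population beside Th2-like cells that expressed Th2 and Th1 regulators together. Cluster 2 held 1521 infected and 122 naive cells, and in the infected library it read Gata3 at 669 CPM, Il4 at 284, Il5 at 49.3 and Epas1 at 627 CPM, below the 917, 386, 55.3 and 883 CPM of Th2-like cells. Il13 was far lower, at 23.3 against 170 CPM (log2 ratio -2.86), and Csf2 was higher, at 248 against 96.5 CPM (1.36). It read Tbx21, the Th1 regulator, at 188 CPM, and Ifng, Cxcr3 and the residency gene Itga1 at 43.3, 86.0 and 45.0 CPM, against 10.5, 3.17, 4.38 and 2.17 CPM in Th2-like cells. The stress genes Hspa1b and Hspa1a were among its 10 leading genes, at 1205 and 757 CPM in its infected cells against 429 and 277 CPM in Th2-like cells. Th1 genes were not kept out of the clustering, so they describe cluster 2 and are no result of a comparison. At 2000 UMIs, 19.2% of its infected cells (17.2 to 21.3, of 1487) and 19.8% of its naive cells (13.1 to 28.1, of 121) had a UMI of both Gata3 and Tbx21. Independent reading of both genes within the cluster would give 19.7% and 20.2%. In Th2-like cells the share was 1.35% of infected and 3.54% of naive cells, and in Th1-like cells 10.1% and 5.59%. The median doublet score of infected cells was 0.0980 in cluster 2 and 0.119 in Th2-like cells. Since the doublet caller had not worked, these scores cannot decide whether doublets contribute to cluster 2.

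Trbv13-2 was the most frequent T cell receptor beta segment in Th2-like cells and held a larger share in innate-like cells. Among infected Th2-like cells with a Trbv call, Trbv13-2 was the most frequent segment at 13.6% (12.6 to 14.7), and Trbv5 followed at 9.64%. Among naive Th2-like cells Trbv13-2 had 19.3% (14.3 to 25.1) and Trbv20 14.8% (10.4 to 20.1). The entropy of segment use on 223 cells of each library was 3.69 in the naive and 3.95 in the infected cells. In cluster 2 Trbv13-2 had 13.9% of naive and 17.4% (15.5 to 19.5) of infected cells. In innate-like T cells Trbv13-2 had 42.8% (40.1 to 45.6) of naive and 38.5% (26.7 to 51.4) of infected cells, and the entropy on 65 cells was 2.63 and 2.46. Over all retained cells Trbv13-2 had 12.5% and 13.8%.

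Among barcodes that failed the filters, Ccr7 was at 992 CPM in the naive and 997 CPM in the infected library, although passing cells differed, and Ctrb1 of the pancreas was at 0.978 and 32.8 CPM. Ribosomal genes took 25.9% and 23.6% of UMIs, T cell receptor segments 0.270% and 0.215%, and the 10 most abundant genes 9.83% and 10.0%.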
